A study of Caenorhabditis elegans with 3 samples.

How the data were processed

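RNA from 3 preparations of late L3 to early L4 C. elegans hermaphrodites was compared with a wild-type mixed reference RNA on 2-colour arrays, 1 array per preparation. Per the labels, channel 1 held the reference and channel 2 the larval RNA, and no dye swap is described. The authors deposited 1 table of log2 ratios, with 20000 features and 3 columns, and 0 columns of per-sample values were left unused. The scale is not stated and was read from the values. For ratios below 3, 2 raised to each deposited value was a number with 3 decimals in 100% of cases on each array (tolerance 0.01 of the last decimal). With base 10 the share was at most 2.41% and with base e at most 2.45%. The deposited log2 values therefore come from ratios rounded to 3 decimals, and the lowest ratios (0.016, 0.017 and 0.004 on the 3 arrays) rest on few digits. The deposited columns had medians of 0.048, -0.012 and -0.019, so the values were centred near 0, but the rule used, the background correction, any filter on weak spots and the software are not given in the sources used here. The direction is unstated too and was taken as channel 2 over channel 1. The spot intensities were not used here, so no filter on dim spots, no correction for intensity-dependent dye bias and no bound for spots near background could be applied. The interquartile range of the deposited values was 0.94, 1.16 and 0.76 on arrays 1, 2 and 3.

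Features were named through the platform's annotation table, in which 15655 features have 1 gene symbol, 198 have several and 4147 have none. Through the NCBI gene identifier, 15569 of the named features matched a current gene table (assembly WBcel235, used for names and gene lengths only), and 86 kept the annotation's own symbol. Features with several symbols or none stayed unnamed. The 15655 named features stand for 15168 genes, and 467 genes had more than 1 feature. Of the 426 such genes with several features on all 3 arrays, the features' mean log2 ratios differed by a median of 0.28 and by over 1 in 15 genes. Of the genes named in the text by rule, atp-1 has 2 features, with means of 1.76 and 1.98. The positions and sequences of the features were not used here, and features of gene families with near-identical members (major sperm proteins, histones, collagens) may share signal.

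Each array's median was subtracted, features of the same gene were averaged per array, and genes and unnamed features with a value on all 3 arrays were kept (19254). The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. With 1 group, the ratio against 0 is the comparison the design gives, and a common reference carries no spread of its own in this test. The 29 gene lists, fixed before the data were examined, were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 29 lists. Lists needed at least 3 measured genes. Members of a list were also adjusted over the list alone. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

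The genes named follow a rule fixed before the data were examined. They are the 8 named genes with the highest and the 8 with the lowest mean among those past the threshold with the same sign on all 3 arrays. To these were added the 2 members furthest in the list's direction for each list that passed camera, and the 1 member furthest from 0 for each other list. Further members named in the text were chosen after their values were seen.

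The gene test was tested on simulated data with the spread of the real genes, over 19254 genes and 5 runs with 200 changed genes each. It recovered 14.6% of genes changed by 2-fold and 95.8% of genes changed by 4-fold. Of all its calls 4.83% were false, and 0 had the wrong sign. The adjusted threshold is stricter when few genes change, and the real data had 3185 calls. These shares therefore hold for the simulated setting only. Changes near 2-fold can still be missed, but the share missed in the real data was not estimated. The alternatives were the deposited values without centring, arrays scaled to a common spread, quantile normalization, a filter at 2 arrays, each feature on its own, robust empirical Bayes, a test against 1.2-fold, an estimated correlation in camera, and leaving out each preparation in turn. In the runs that left out a preparation, a gene's own spread counts for less than in the main test. No array was found to repeat another, since 0 genes or features had identical values on any pair.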

Results

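Transcript levels were compared between Caenorhabditis elegans hermaphrodites at the late L3 to early L4 larval stage and a wild-type mixed reference RNA on 2-colour microarrays. C. elegans is a nematode that passes through a series of larval stages separated by molts, and in hermaphrodites the germ line makes sperm in the last larval stage and oocytes in the adult. The larval RNA came from 3 preparations, and each was hybridised with the reference on an array of its own. The design therefore gives 1 group of 3 arrays and 1 comparison, larval RNA against the reference. The table held 20000 array features, of which 19908, 19796 and 19840 had a value for preparations 1, 2 and 3. After features of the same gene were averaged, 15077 named genes and 4177 unnamed features had a value on all 3 arrays. Values below are mean log2 ratios of larval over reference RNA with the SD over the 3 preparations (n = 3). The labels do not say whether the preparations came from separate cultures, so the p-values measure only the spread between these preparations. The comparison leaves out the spread of the reference itself, and the number of arrays limits the precision. No dye swap is described, so a dye bias shared by all 3 arrays would count as a difference in this test.

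The direction of the ratio is likely larval over reference, but the table does not state it. The labels put the reference in the first channel and the larval RNA in the second, and describe each array as larvae against reference. A check fixed beforehand used yolk and eggshell genes, which adults and embryos express. The eggshell and egg activation list had a median log2 ratio of -2.31, -1.97 and -3.09 on arrays 1, 2 and 3. The vitellogenins had medians of 0.07, -0.69 and 0.14 over 3 measured genes, and the best separated of these, the yolk protein gene vit-2, lay at -4.74 ± 1.49. Without preparation 2 the vitellogenin median over arrays was above 0, at 0.11, so this list bears on the direction less than the eggshell genes do. Were the ratio turned the other way, every sign given here would turn with it, and higher and lower would change places in every count and share.

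The 3 preparations resembled each other moderately. Across the 19254 genes and features, Pearson's r was 0.52 between preparations 1 and 2, 0.70 between 1 and 3, and 0.61 between 2 and 3. Spearman's rho was 0.39, 0.57 and 0.50 for the same pairs. These correlations run across genes, which are not independent replicates. The SD of a gene over the preparations had a median of 0.43 on the log2 scale, against an SD of 0.75 for the mean ratios across genes. The log2 ratio had the same sign on all 3 arrays for 47% of genes and features, where chance alone gives 25%.

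Larval RNA differed from the reference at 3185 of the 19254 genes and features, with 1668 higher and 1517 lower (limma, adjusted p under 0.05). The highest named genes included infection-response, detoxification and metabolic genes, and the lowest included uterine and eggshell genes. irg-5 (NCBI gene 185307), an infection response gene, was highest at 5.99 ± 0.29, or 63.4-fold (limma adjusted p = 3.26e-10). It was followed by acdh-1, an acyl-CoA dehydrogenase gene, at 4.38 ± 0.41 and by a second infection response gene, irg-8, at 4.24 ± 0.72. The heme-responsive gene hrg-7 lay at 4.19 ± 0.20, the glucuronosyl transferase gene ugt-22 at 4.02 ± 0.14 and the cathepsin B-like protease gene cpr-5 at 3.95 ± 0.23. bcf-1 at 3.92 ± 0.51 and dod-19 at 3.86 ± 0.42 completed the 8 highest named genes.

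The lowest named gene was D1054.10 (NCBI gene 179496) at -5.54 ± 0.64, or 46.5-fold lower (limma adjusted p = 2.22e-09). ZK813.3 at -5.45 ± 1.16, ZK813.1 at -5.11 ± 1.36 and C44B7.5 at -5.10 ± 0.92 came next. perm-2, which encodes a protein of the eggshell permeability barrier, lay at -5.05 ± 1.40. ule-4 and ule-3, named for their expression in the uterine lumen, lay at -4.94 ± 0.98 and -4.86 ± 1.21, and stha-3 at -4.80 ± 0.82. The SDs ran from 0.64 to 1.40 among the 8 lowest genes and from 0.14 to 0.72 among the 8 highest. Without preparation 1, ZK813.1 moved to -5.89. Without preparation 2, perm-2 moved to -5.86, and without preparation 3, ZK813.3 moved to -4.79 and ule-3 to -4.17. Changes of at least 4-fold were found for 234 higher and 286 lower genes and features, and changes of at least 16-fold for 7 and 26. A called gene or feature had a mean of at least 0.81 in size, and 60 of the 3185 calls did not have the same sign on all 3 arrays. Leaving out preparation 3 reduced the counts to 904 higher and 838 lower.

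**Figure D1:**
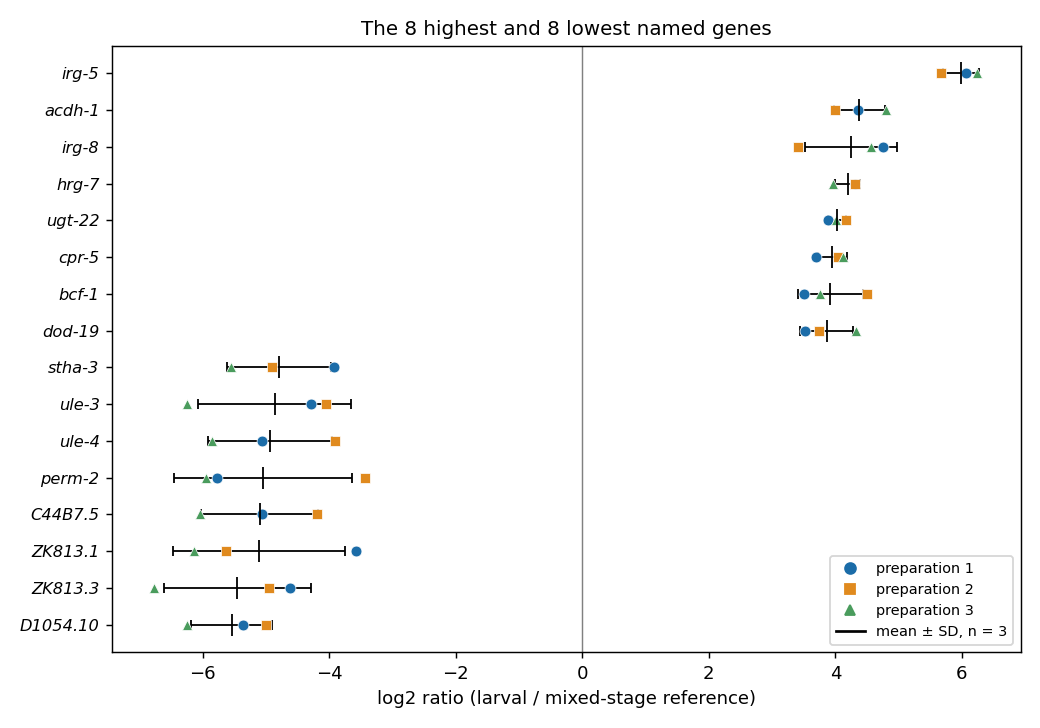
Log2 ratio of larval over reference RNA on the x axis for the 8 highest and 8 lowest named genes, with 1 point per preparation and the mean ± SD (n = 3) as a black line. irg-5 has the highest mean at 5.99 and D1054.10 the lowest at -5.54, and all points of a gene lie on one side of 0.

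Among the 29 fixed lists, those of eggshell and oocyte genes had the medians furthest below the reference. All 13 measured genes of the oocyte and maternal regulators list were lower, with a median 4.28-fold below the reference. Among them were puf-5, an RNA-binding regulator of oocytes, at -3.33 ± 0.62 and oma-2, a regulator of oocyte maturation, at -2.88 ± 0.83. Of the 10 eggshell and egg activation genes, 8 were lower and the list's median was -2.47. perm-2 and the chondroitin proteoglycan gene cpg-3, at -3.92 ± 0.69, led this list, and its members cpg-2 and egg-1 did not pass the test at -0.06 and -0.03. The counts were the same when adjusted over the list alone, 13 and 8. Both lists passed limma's camera test (adjusted p = 1.65e-14 for the oocyte list and 2.83e-11 for the eggshell list). Camera asks whether the test statistics of a list's genes differ on average from those of all other genes, so it does not test the median. With an estimated correlation between genes in place of the preset 0.01, both had an adjusted p = 0.33. That version of camera has only 2 residual degrees of freedom here, and 0 lists passed it, with 3 at an unadjusted p under 0.05.

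The vitellogenin list had 3 measured genes of 6 and did not pass camera (median -0.16, mean -1.59, adjusted p = 0.084). vit-2 was lower by 26.6-fold (limma adjusted p = 1.79e-07), with -5.47 without preparation 2 and -3.98 without preparation 3. vit-5 and vit-6 did not pass at -0.16 and 0.12. The list did pass camera without preparation 1 (median -0.27) and without preparation 3 (median -0.31). Of the 8 measured members of the list named early embryonic zygotic factors, 1 was lower, the homeodomain gene pal-1 at -2.02 ± 0.38. The other 7 did not pass (list median -0.05, camera adjusted p = 0.60). Whether the pal-1 RNA in the reference was maternal or zygotic cannot be told from these arrays. The adjustments over the list alone gave the same count of 1 for both lists.

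Germline genes did not move as a block. Among 18 core germline genes, 6 were higher, 1 was lower and 11 did not pass. The median was 0.00 and the mean 0.44, with a camera adjusted p = 0.058. Adjusted over the list alone, 6 were higher and 2 lower. The list passed camera as higher without preparation 2 (median 0.14) and without preparation 3 (median 0.02). The germ granule helicase gene glh-1 was the furthest from 0 at 2.89 ± 0.57, and its relatives glh-2 and glh-4 were higher too, at 1.60 and 1.49. Genes of meiotic chromosomes were lower as a list, with 7 of 18 lower, none higher and a median of -0.69 (camera adjusted p = 5.67e-04, and adjusted p = 0.44 with an estimated correlation). lab-1 at -1.65 ± 0.41 and the synaptonemal complex gene syp-3 at -1.31 ± 0.31 led this list, and 9 members were lower when adjusted over the list alone. Of 17 mitotic cell cycle genes, 4 were lower, including the cyclin B gene cyb-3 at -1.59 ± 0.48 and cdk-1 at -1.21 ± 0.60, and adjusted over the list alone the count was again 4. That list had a median of -0.34 (camera adjusted p = 0.020, and adjusted p = 0.50 with an estimated correlation), and it did not pass without preparation 1, with a median of -0.30. cdk-1 itself did not pass without preparation 1, with -0.88. DNA replication genes did not pass as a list (median -0.30, camera adjusted p = 0.10). psf-1, a subunit of the GINS replication complex, was the only one of the 18 to pass over all genes, at -0.89 ± 0.17 (limma adjusted p = 0.034), and 0 of the 18 passed limma's test when adjusted over the list alone, with 4 lower at an unadjusted p under 0.05. Without preparation 1 or preparation 3, psf-1 did not pass, with -0.80 and -0.89. Histone genes lay near 0, with a median of 0.02, 1 of 55 higher (his-70 at 1.32 ± 0.56) and a camera adjusted p = 0.50. Adjusted over the list alone, the histone count was also 1.

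The 2 sperm lists had medians of opposite sign, but neither kept its call when each preparation was left out in turn. The difference between them was not tested. Of 17 sperm genes other than the major sperm proteins, 6 were higher, 1 was lower and 10 did not pass, with a median of 0.39 (camera adjusted p = 0.032, and adjusted p = 0.36 with an estimated correlation). The higher members included spe-41, a sperm calcium channel gene, at 1.84 ± 0.96 and fer-1, needed for membrane fusion in sperm, at 1.45 ± 0.58. The lower member was spe-27 at -1.29, and over the list alone 7 were higher and 1 lower. Without preparation 3, fer-1 did not pass at 1.12, and without preparation 1 the list did not pass, with a median of 0.40. The major sperm protein genes, whose near-identical sequences may share signal, had a median of -0.34, and 0 of 30 passed limma's test over all genes or adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. The 2 lowest were msp-59 at -0.95 ± 0.90 (limma adjusted p = 0.052) and msp-51 at -0.87 ± 0.94 (limma adjusted p = 0.081), and both passed without preparation 1, at -1.46 and -1.41. The list passed camera (adjusted p = 0.035, and adjusted p = 0.72 with an estimated correlation), although its array medians were 0.29, -0.46 and -0.79. Its median was -0.60 (adjusted p = 2.9e-04) without preparation 1, -0.25 (adjusted p = 0.28) without preparation 2 and -0.12 (adjusted p = 0.62) without preparation 3.

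**Figure D2:**
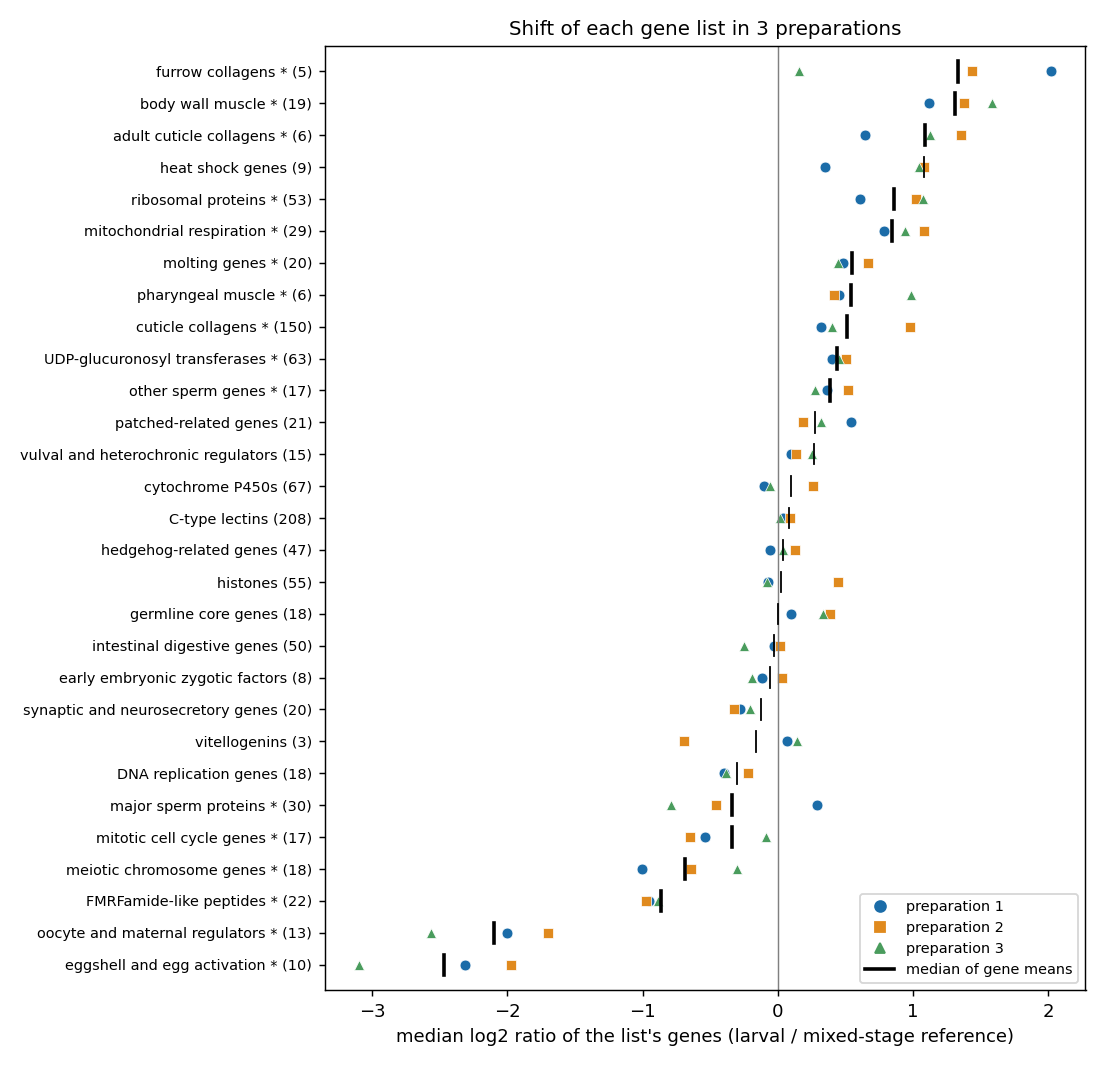
Median log2 ratio of each of the 29 gene lists on the x axis, with 1 point per preparation and a black bar at the median of the gene means. An asterisk and a thick bar mark lists that passed camera with the preset correlation, and the number of measured genes is in parentheses. The eggshell genes have the lowest median, at -2.47, followed by the oocyte genes, and the furrow collagens spread most widely between preparations.

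Cuticle collagen genes were called in both directions, though genes of similar sequence may share signal. Of 150 cuticle collagen genes, 66 were higher, 30 were lower and 54 did not pass, with a median of 0.51. Adjusted over the list alone, 69 were higher and 36 lower. bli-1, a collagen of the struts that support cuticle layers, lay at 3.35 ± 1.70 and col-117 at 3.35 ± 0.80. The list passed camera (adjusted p = 2.9e-04, and adjusted p = 0.50 with an estimated correlation). All 5 measured furrow collagens, which build the annular furrows of the cuticle, had means above 0 (median 1.33), with 4 passing over all genes and 5 over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.44 with an estimated correlation). dpy-9 lay at 1.63 ± 0.93 and dpy-3 at 1.34 ± 0.86, and the array medians of the furrow list were 2.02, 1.434 and 0.16. Without preparation 1 the furrow list did not pass, with a median of 0.67, and dpy-3 did not pass at 1.00.

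Of 6 collagens described as adult-enriched, 4 were higher and 1 was lower, in both adjustments, and the list's median was 1.09 (camera adjusted p = 0.024, and adjusted p = 0.36 with an estimated correlation). bli-1 and bli-2 (2.99 ± 1.70) were higher, as were col-7 and rol-6, while the adult collagen gene col-19 was lower at -2.87 ± 0.46. Without preparation 3, bli-1 moved to 4.33 and bli-2 to 3.92, and without preparation 1 bli-2 moved to 2.25. Molting genes were higher as a list, with 6 of 20 higher, none lower and a median of 0.55 (camera adjusted p = 5.67e-04, and adjusted p = 0.33 with an estimated correlation). Over the list alone, 9 were higher and 1 lower. noah-2 and noah-1, which encode apical matrix proteins, led it at 2.09 ± 1.21 and 1.98 ± 1.27. noah-1 moved to 1.28 without preparation 1, and noah-2 to 2.78 without preparation 3.

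**Figure D3:**
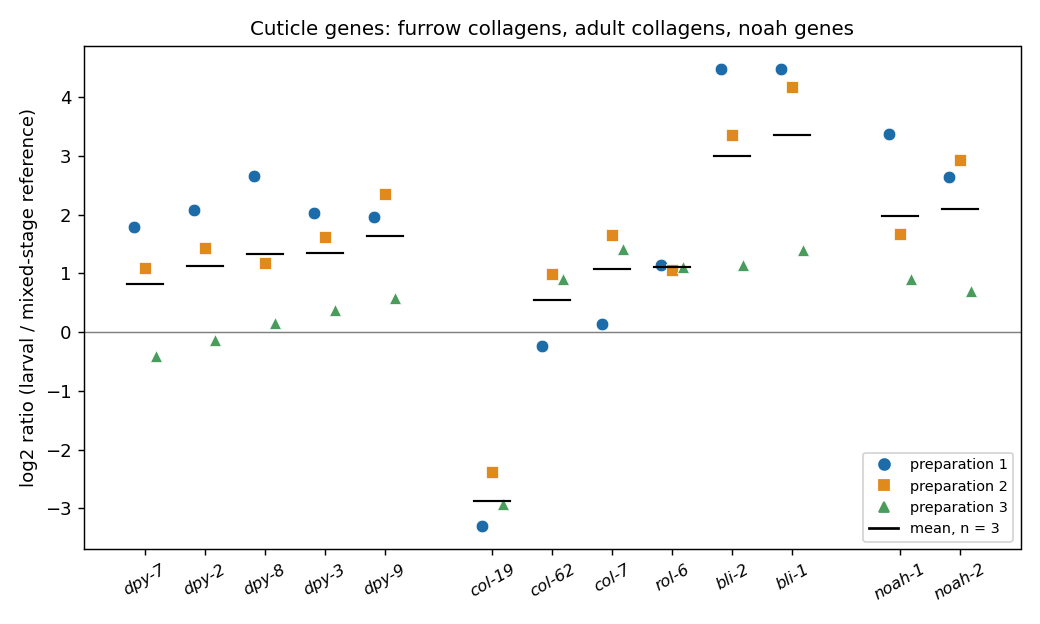
Log2 ratio of larval over reference RNA on the y axis for the 5 furrow collagens, the 6 adult-enriched collagens and the 2 noah genes, with 1 point per preparation and a black line at the mean (n = 3). Preparation 3 lies lowest for every furrow collagen, for bli-1 and bli-2 and for both noah genes, and col-19 lies below 0 in all preparations.

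Neither of the gene families related to molting signals passed as a list. Hedgehog-related genes had 3 of 47 higher and 9 lower, with a median of 0.04 but a mean of -0.15 (camera adjusted p = 0.50, direction down). The ground-like gene grl-3 was furthest from 0 at -2.33 ± 0.85, and over the list alone 5 were higher and 9 lower. Patched-related genes had 2 of 21 higher, led by ptr-11 at 1.39 ± 0.19, with a median of 0.27 (camera adjusted p = 0.084), and of 0.51 without preparation 1. Over the list alone 1 patched-related gene was higher. None of 15 vulval and heterochronic regulators was higher and 1 was lower, hbl-1 at -0.85 (median 0.27, camera adjusted p = 0.50). The member furthest from 0 was the beta-catenin gene bar-1 at 0.86 ± 0.54, which did not pass (limma adjusted p = 0.053), and 0 passed limma's test when adjusted over the list alone, with 3 higher and 3 lower at an unadjusted p under 0.05.

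Muscle, ribosomal and mitochondrial genes were higher in larval RNA, on arrays for which no dye swap is described. Whether a dye bias shared by the arrays adds to these shifts was not tested. Of 19 body wall muscle genes, 14 were higher and none lower, with a median of 1.31 (2.48-fold), and the count over the list alone was also 14. unc-52, the perlecan of the muscle basement membrane, lay at 2.74 ± 0.45 and the troponin T gene tnt-2 at 2.60 ± 0.38, while the major body wall myosin gene unc-54 did not pass at 0.19. Of 6 pharyngeal muscle genes, 2 were higher, the myosin gene myo-1 at 2.08 ± 0.55 and tnt-4 at 1.65 ± 0.74, and 3 over the list alone. Camera gave an adjusted p = 8.71e-12 for body wall muscle and 0.022 for pharyngeal muscle. With an estimated correlation, body wall muscle had an adjusted p = 0.33 and pharyngeal muscle an adjusted p = 0.44. Without preparation 3 the pharyngeal list did not pass, with a median of 0.35.

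Of 53 cytosolic ribosomal protein genes, 28 were higher and none lower, with a median of 0.86, and over the list alone 41 were higher. rpl-4 lay at 2.14 ± 0.89 and rps-9 at 1.89 ± 0.31. Of 29 respiratory chain and ATP synthase genes, 15 were higher and none lower, with a median of 0.85, and 19 were higher over the list alone. The ATP synthase subunit genes atp-2 and atp-1 lay at 2.22 ± 0.15 and 1.87 ± 0.13. Camera gave an adjusted p = 4.08e-14 for the ribosomal list and 2.46e-10 for the respiratory list, and with an estimated correlation both had an adjusted p = 0.33.

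Neuropeptide genes were lower, while the synaptic and neurosecretory genes did not pass as a list, on arrays for which no dye swap is described. Of 22 FMRFamide-like peptide genes, 12 were lower and none higher, with a median of -0.86 and 15 lower over the list alone. flp-1 lay at -2.09 ± 0.34 and flp-12 at -1.72 ± 0.81. The list's array medians of -0.95, -0.97 and -0.89 differed little (camera adjusted p = 5.96e-09, and adjusted p = 0.33 with an estimated correlation). Of 20 synaptic and neurosecretory genes, 3 were lower, 17 did not pass and the median was -0.12 (camera adjusted p = 0.084). The array medians of this list were lower than that, at -0.28, -0.32 and -0.20. The 3 were sbt-1, which encodes the neuropeptide processing chaperone 7B2, at -1.88 ± 0.39, with ric-4 at -1.41 and ida-1 at -1.10. Over the list alone 4 were lower.

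Glucuronosyl transferase genes, which act in detoxification, were higher as a list. Of 63, 20 were higher and 2 lower, with a median of 0.44 (camera adjusted p = 3.87e-06, and adjusted p = 0.33 with an estimated correlation). ugt-22 and ugt-16, at 2.73 ± 0.59, led it, and over the list alone 24 were higher and 4 lower. Cytochrome P450 genes divided evenly, with 8 of 67 higher and 8 lower in both adjustments (median 0.10, camera adjusted p = 0.60), and cyp-35C1 was furthest from 0 at 3.53 ± 0.74. Intestinal digestive genes did likewise, with 9 of 50 higher and 8 lower, and 14 and 9 over the list alone (median -0.03, mean 0.06, camera adjusted p = 0.79, direction up). cpr-5 was the member furthest from 0. C-type lectin genes had 19 of 208 higher and 16 lower in both adjustments (median 0.08, camera adjusted p = 0.60), and clec-91 lay at -3.77 ± 0.62.

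Heat shock genes were included as a sign of handling stress, and they did not pass as a list (median 1.08, camera adjusted p = 0.070), except with the arrays scaled to a common spread (median 1.10). Without preparation 2 the list's median was 0.65. Of 9 measured, 6 were higher and 1 was lower, and over the list alone 6 and 2. That the list did not pass therefore does not exclude handling stress. The lower gene was the small heat shock protein gene hsp-12.6 at -4.46 ± 0.95, and the list's mean was 0.34, below its median. Among the higher ones were hsp-3, a chaperone gene of the endoplasmic reticulum, at 2.66 ± 0.44 and hsp-16.1 at 1.08, and hsp-70 and hsp-16.48 did not pass at -0.77 and -0.21. The array medians of this list were 0.35, 1.08 and 1.05.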

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

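The gene counts stayed within 1.5 times 1668 higher and 1517 lower under every alternative but 2. Testing against 1.2-fold in place of 0 gave 1032 higher and 981 lower, as its stricter null requires. Leaving out preparations in turn gave 904 to 1802 higher and 838 to 1895 lower, lowest without preparation 3 and highest without preparation 2; without preparation 3, 860 of the 1668 higher and 795 of the 1517 lower genes and features were still called. Camera called 10 lists higher and 6 lower, and leave-one-out runs gave 8 to 11 and 5 to 6. The furrow and adult collagen lists are parts of the cuticle collagen list, so these counts are not of separate sets of genes. With an estimated correlation the counts were 0 and 0 and the lowest adjusted p was 0.33, with 3 lists at an unadjusted p under 0.05. The lists that lost their call there have the same medians by construction: eggshell -2.47, oocyte -2.1, FMRFamide-like -0.86, meiotic -0.69, mitotic -0.34, major sperm proteins -0.34, other sperm 0.39, glucuronosyl transferases 0.44, cuticle collagens 0.51, pharyngeal muscle 0.54, molting 0.55, respiration 0.85, ribosomal 0.86, adult collagens 1.09, body wall muscle 1.31 and furrow collagens 1.33.

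Heat shock genes passed camera with arrays scaled (median 1.10). With genes on at least 2 arrays, where cameraPR replaced camera, vitellogenins passed (-0.16), germline core genes passed as higher (median 0.00322) and major sperm proteins did not (-0.34). On genes measured on all 3 arrays, a check chosen after the data were seen, cameraPR called 11 lists higher and 6 lower, with the same 3 differences, so the tool rather than the filter gives them. The estimated correlation changes both the degrees of freedom, to 2, and the correlation itself, and their parts were not separated. Among the lists that had passed, the estimate ran from -0.09 for the adult collagens to 0.91 for the furrow collagens. It was 0.71 for the major sperm proteins and 0.43 for oocyte genes. For most lists that passed, the preset of 0.01 lay below the estimate, so their calls may depend on it. Germline core genes also passed with each feature on its own (0.00398). Vitellogenins passed without preparation 1 or 3, and germline core genes without 2 or 3. The cause of the other changes was not tested. Over the runs that each left out 1 preparation, list medians ranged as follows: vitellogenins -0.31 to 0.11, major sperm proteins -0.60 to -0.12, other sperm genes 0.27 to 0.56, mitotic genes -0.31 to -0.26, germline core genes 0.0193 to 0.14, furrow collagens 0.67 to 1.82, pharyngeal muscle 0.35 to 0.72, heat shock genes 0.65 to 1.30, patched-related genes 0.24 to 0.51, early embryonic factors -0.11 to -0.0349, synaptic genes -0.25 to -0.22, vulval and heterochronic regulators 0.18 to 0.37, hedgehog-related genes -0.00241 to 0.059, cytochrome P450s -0.0227 to 0.0527, histones -0.0292 to 0.119, intestinal digestive genes -0.12 to 0.00596 and C-type lectins 0.0212 to 0.10. Without preparation 2 the vitellogenin median turned to 0.11 and the cytochrome P450 median to -0.0227, without preparation 1 the hedgehog-related median turned to -0.00241, and without preparation 2 camera's direction turned for histones (-0.0292), intestinal genes (-0.0611) and C-type lectins (0.0212), none of which had passed. Of the genes named by rule, none changed direction, and msp-59 and bar-1 passed under quantile normalization and robust empirical Bayes. psf-1 did not pass limma's test against 1.2-fold (adjusted p = 0.13). No paired analysis was possible because there is only 1 group. Arrays limit precision by their number, and no signal over background was at hand. Reversing the sign of 1 array at a time gave 0 called genes by limma in each of the 3 cases (49 to 240 at an unadjusted p under 0.05, against 5438), against 3185 for the arrays as they stand; the real arrays were 1 of the 4 sign patterns to reach that count, and 4 patterns are too few for a share under 0.05.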

Other observations

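Gene families outside the fixed lists were examined with a camera test of 188 families of at least 8 genes that share a symbol prefix, a test chosen after the data were seen. Of the 151 families with no member in a fixed list, 15 passed at an adjusted p under 0.05, and none of these did with an estimated correlation (adjusted p = 0.89 for each family named here). The families named kept their direction and their call without centring, with arrays scaled, with quantile normalization and without each preparation in turn, although without preparation 2 the pals median was -0.38. Neuropeptide-like protein genes (nlp) were lower, with 25 of 53 lower, none higher and a median of -0.82 (adjusted p = 8.48e-09), led by nlp-8 at -2.43 ± 0.52. Transthyretin-related genes (ttr) had 13 of 46 lower and none higher (median -0.45, adjusted p = 1.74e-05), and pals genes had 9 of 24 lower and none higher (median -0.60, adjusted p = 3.52e-05), led by pals-39 at -3.20 ± 1.02 and at -3.78 without preparation 2. Vacuolar proton pump genes (vha) were higher, with 11 of 17 higher and 1 lower (median 1.24, adjusted p = 5.56e-06), and the intestinal subunit gene vha-6 lay at 2.76 ± 0.32. The abu genes had the highest median of these families, with 8 of 13 higher and none lower (median 1.81, adjusted p = 2.68e-07), but their array medians were 0.75, 1.52 and 3.15. In preparation 3, 12 of the 13 abu genes lay above the mean of the others, by a median of 1.75, and the family's median was 2.67 without preparation 1 and 1.01 without preparation 3. Acyl-CoA dehydrogenase genes had 6 of 11 higher and none lower (median 0.90, adjusted p = 3.87e-04). The infection response genes did not move alike: irg-5, irg-8, irg-4 (3.58 ± 0.52) and irg-7 (2.72 ± 0.02) were higher, while irg-1, irg-2 and irg-6 did not pass at -0.16, -0.50 and 0.50; without preparation 1, irg-6 passed at 1.29. The lowest of all features were unnamed, and feature 2714495 was lowest at -6.21 ± 1.51, with -5.34 without preparation 3. In preparation 3 it shared the value -7.95 with features 2716985 and 2717027. This was the lowest ratio of that array, 0.004, which rests on few digits, so the order among these features is uncertain. The highest unnamed feature, 2709345, lay at 5.16 ± 1.13, with 4.51 without preparation 2.

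Among the tests of explanations below, those on synaptic genes and on the furrow collagens in preparation 3 were chosen after the result was seen. The 75 neuropeptide genes (22 flp and 53 nlp) had a median of -0.85, while synaptic genes had a median of -0.12, which was -0.23, -0.22 and -0.25 without preparations 1, 2 and 3. For weak spots that read low in the larval channel, 1090 serpentine receptor genes, which few neurons express, were examined. Their median was -0.0305 with a lower bootstrap bound of -0.06, above -0.42, the bound set before this test at 0.5 of the neuropeptide median. That median includes the 53 nlp genes, which were picked after the data were seen, so the bound was not fixed independently of the data. That these spots are weak is assumed, as intensities were not used here. The receptors therefore cannot decide on this explanation, which stays open. Short genes that read low are argued against by 10000 lists of other genes matched on gene length, whose medians had a middle value of -0.0518 and a 2.5th percentile of -0.21. For a smaller share of neuronal RNA as the whole cause, the synaptic median lay 0.72 above the neuropeptide median (permutation test over genes, two-sided, 100000 permutations, p = 0.0018). In permutation tests without preparations 1, 2 and 3 the difference was 0.71 (p = 0.00249), 0.58 (p = 0.0194) and 0.54 (p = 0.0133), though genes are not independent replicates. The 53 nlp genes come from a family test chosen after the data were seen, and the difference itself was seen before it was tested. The p-values therefore restate the pattern and cannot decide on this explanation, which stays open. A stage difference in neuropeptide expression may remain as a hypothesis, and dye bias at these spots stays open without a dye swap.

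The furrow collagens lay lower in preparation 3, where all 5 were below the mean of preparations 1 and 2 with a median deviation of -1.76; over all 150 cuticle collagens the median deviation was -0.0277, with 76 below, and over the 6 adult-enriched collagens it was -0.0402, with 3 below, among them bli-1 (4.48, 4.18 and 1.40 in preparations 1, 2 and 3) and bli-2 (4.48, 3.35 and 1.14), while over all genes preparation 3 had the smallest deviation from the others (MAD 0.536, against 0.623 and 0.750 for preparations 1 and 2). Compression of all ratios on that array is argued against by the eggshell, oocyte and body wall muscle lists, the lists outside the cuticle with medians of at least 1 in size in both other preparations, whose 42 genes lay further from 0 in preparation 3 by a median of 0.46 (bootstrap interval 0.39 to 0.72). Independent noise of single spots is argued against, since among 10000 draws of 29 random lists of the same sizes, the largest deviation over all lists and preparations was as large in 0.11% of draws. Preparations taken at different points of the molting cycle are a possible explanation that stays open: the 20 molting genes had a median deviation of -0.39 in preparation 3, with 15 below and 5 above, and the 18 other than noah-1 and noah-2, which had been seen to deviate, differed by a median of 0.48 in size, against 0.38 for random lists matched on mean ratio, and 16% of those lists differed as much. In the other direction, 12 of the 13 abu genes lay above the mean of the others in preparation 3, by a median of 1.75. Whether the abu and furrow collagen deviations share a cause was not tested. Signal shared between furrow collagens of similar sequence and a batch difference between arrays were not tested and stay open too.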
